A study of Homo sapiens with 2 samples.

How the data were processed

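Single-cell RNA was measured in 2 libraries of K562, a human chronic myeloid leukaemia cell line that carries the BCR-ABL fusion. Per the labels, the cells expressed Cas9 and received a lentivirus with a pair of guide RNAs against a chromatin hub named HUB162 or HUB161, were grown for 10 days and were sorted for both fluorescent markers. Each group, HUB162-KO and HUB161-KO, held 1 library. The positions of both hubs and the guide sequences are not given in the sources used here, so loss of the targets was not checked.

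The deposited matrices held UMI counts per gene and barcode from the 10x 3′ v3 protocol, without a filter for cells. Cell Ranger 7.0.0, Seurat 4.1.0 and GRCh38 are named in the submitters' processing notes, while the header of the matrices names another release of Cell Ranger. The annotation and the setting for intronic reads are not given in the sources used here, so UMIs of a long noncoding RNA inside or against another gene could not be apportioned. A deposited table of counts for 15322 gene symbols had 30 columns for HUB162-KO and 26 for HUB161-KO. These columns are sums over groups of cells of 1 library and were not treated as replicates, and how the authors made the groups is not given in the sources used here.

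The matrices held 36601 genes and 174685812 UMIs for HUB162-KO, and 175492028 UMIs for HUB161-KO. Barcodes counted as cells when their UMIs reached 0.1 of the 99th percentile of the top barcodes, with the number of top barcodes chosen to predict its own call. This set the lowest UMI total at 4111 for HUB162-KO and 6465 for HUB161-KO. Cells with fewer than 500 genes or with 20% or more mitochondrial UMIs were removed, which left 10236 and 6784 cells. Scrublet, run in scanpy 1.11.5 with an expected rate of 6%, called 0 and 3 cells doublets. A share of 0.0442% in the second library is too low to be credible, so the caller did not work on these cells, and doublets of 1 cell line stayed in.

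UMIs were summed over the cells of a library and divided by the summed total to give CPM, the usual unit of UMIs scaled for library size. Genes with a mean CPM of at least 5 counted as measured, a sum under 3 was set to 3, and ratios are log2 of HUB162-KO over HUB161-KO. A 95% exact Clopper-Pearson interval, which covers counting error only, was computed for named ratios and is printed for some of them. With 1 library per group no test between the groups was possible, and no p-value was computed. A count of genes at least 2-fold apart is a rule of size, not a count of changed genes. The median ratio of each of 36 gene lists was placed among 10000 random lists of the same size matched on mean CPM in 20 bins, and lists with fewer than 5 measured genes got no median. The lists, the markers, the tests and the first set of alternatives were fixed before the data were examined, apart from tests of 3 patterns. Those 3 patterns are given in the closing section.

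Genes were named by a fixed rule. It took the 12 highest and the 12 lowest log2 ratios among measured genes, the 4 members furthest in the direction of each list outside the central 95% of random lists, up to 2 members with the highest mean CPM in other lists, and genes at the ends of the regional windows furthest from 0. Genes named outside the rule are marked as chosen after their values were seen.

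For cell cycle phases each cell was thinned to 5000 UMIs, shallower cells were left out, and scores for S and G2M genes were taken against expression-matched control genes. Cells were clustered together with the Leiden method (leidenalg 0.10.2, resolution 0.8) on 20 principal components of 2000 variable genes and 15 neighbours. A cluster was called erythroid-like only where at least 3 of the fixed markers stood among its top 10 genes by fold. Positions, and the GC content and length of the Ensembl canonical transcript, came from GENCODE release 44 on GRCh38, matched on Ensembl gene ID for 10758 of 10777 measured genes. The GC content was first taken from each gene's longest transcript and was moved to the canonical transcript after results had been seen, so both versions are reported. Windows of 25 neighbouring measured genes were compared with 1000 shuffles of gene order.

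Alternatives covered normalization (the TMM factor of edgeR 4.0.16), the expression minimum, cell weights, cell filters, phases, thinning, window size and clustering. The ratio step was tested on simulated data with folds put on 4 sets of 50 of the 10777 measured genes, and 10748 genes passed the expression minimum in the simulated counts. All 50 genes at a fold of 2.5, all 50 at 4 and all 50 at 0.25 came out at least 2-fold apart, as did 0 of 50 at 1.5 and 0 of the 10577 others. The counting intervals covered the simulated value in 96.0%, 94.0%, 88.0% and 92.0% of genes at folds of 1.5, 2.5, 4 and 0.25, and in 95.2% of genes without a fold. In the same simulation 1 of 40 random lists fell outside the central 95%. Those simulated ratios had no GC trend and the lists were drawn at random, so this rate need not hold for the real lists. Analyses used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.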

Results

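The data described K562 cells 10 days after Cas9 was directed at either of 2 chromatin hubs, which the labels name HUB162 and HUB161. The sample titles call the first "Ess" and the second "Noness". Each hub was represented by 1 sorted library, so no value below has a replicate, and every interval covers counting error only. The HUB162-KO library gave 10236 cells with a median of 14051 UMIs and 4401 genes, and the HUB161-KO library gave 6784 cells with a median of 20706 UMIs and 5289 genes. Median mitochondrial shares were 2.45% and 2.87%, and median ribosomal protein shares were 24.2% and 25%. The cells held 162044572 and 158904917 UMIs, so the sums per gene were about equally deep although HUB162-KO cells were shallower.

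The first comparison asked which genes differed in level between cells targeted at the HUB162 and HUB161 hubs. The libraries were nearly alike. The log2 ratios of 10777 measured genes had an SD of 0.17, and 13 genes were at least 2-fold higher in HUB162-KO and 0 were at least 2-fold lower. Among the 12 highest ratios the genes with the highest levels were SNHG9, a small nucleolar RNA host gene, NMT1, which encodes an enzyme that attaches myristate to proteins, and HES1, a transcriptional repressor downstream of Notch. SNHG9 stood at 159 CPM in HUB162-KO and 63.0 CPM in HUB161-KO, a 2.52-fold difference (log2 1.33, 95% interval 1.30 to 1.37). NMT1 stood at 289 and 133 CPM (2.17-fold, log2 1.12, 1.09 to 1.14), and HES1 at 108 and 50.5 CPM (2.14-fold, log2 1.10, 1.06 to 1.13). No test across libraries could be made.

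The other genes among the 12 highest were mostly noncoding. The uncharacterised RNA AC103591.3 had the highest ratio, at 11.5 against 3.88 CPM (log2 1.57, 1.44 to 1.71). ARMC3, an armadillo repeat gene, followed at 8.91 against 3.44 CPM (log2 1.37, 1.23 to 1.52). MIR4458HG, a microRNA host gene on chromosome 5 from 8450701 to 8486930 (GRCh38), stood at 60.1 against 27.7 CPM (log2 1.12, 1.07 to 1.17). HIST1H2BA, a histone H2B gene, had a log2 ratio of 1.08, and MAFIP 1.24. The remaining members were AL023803.1 (log2 1.31), AC009107.2 (1.10), AC009292.2 (1.08) and AC010624.5 (1.05). Of these 12 genes 7 were annotated as long noncoding RNA, and 10 were higher in HUB162-KO in each of 12 cell clusters. The clusters are parts of the sums by which these genes were picked, so this is not separate evidence. NMT1 lies on chromosome 17 from 44957992 to 45109016, HES1 on chromosome 3 from 194136148 to 194138732 and SNHG9 on chromosome 16 from 1964895 to 1965509.

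**Figure D1:**
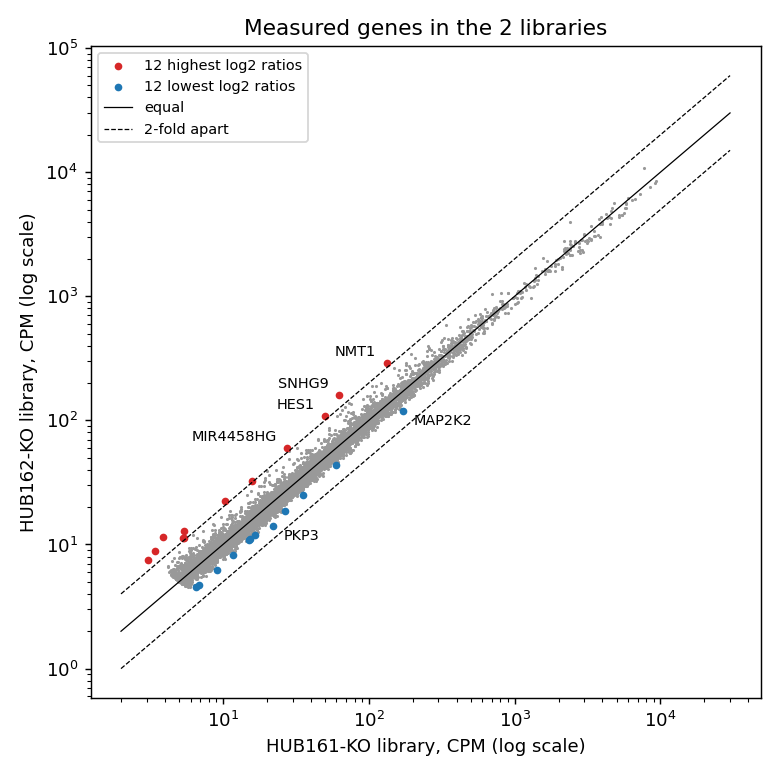
Each grey point is 1 of 10777 measured genes, with its CPM in the HUB161-KO library on the x axis and in the HUB162-KO library on the y axis, both on log scales. The 12 highest ratios (red) include NMT1 at 289 against 133 CPM, and none of the 12 lowest (blue) reaches the dashed line for a 2-fold difference.

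The 12 lowest ratios were smaller in size and belonged to GC-rich genes. PKP3, which encodes the desmosomal protein plakophilin 3, was 1.55-fold higher in HUB161-KO (14.2 against 22 CPM, log2 -0.64, -0.71 to -0.56). MAP2K2, which encodes the kinase MEK2, was 1.43-fold higher there (120 against 171 CPM, log2 -0.52, -0.54 to -0.49). SLC6A8, the creatine transporter gene, stood at 43.4 against 59.5 CPM (log2 -0.46), and FBXW5 at 24.9 against 35.3 CPM (log2 -0.50). The stress-inducible gene GADD45B stood at 4.57 against 6.58 CPM (log2 -0.53), but was lower in only 7 of 12 clusters. The others were PLPPR3 (-0.55), LRRC45 (-0.55), AC004556.3 (-0.54), ZNF205 (-0.52), CCDC22 (-0.48), FAAP100 (-0.46) and ARFGAP1 (-0.46). Median GC of the 11 members with a value was 65.5%, against 47.3% for measured genes. Across measured genes the log2 ratio was lower at higher GC content (Spearman -0.51, across genes, which are not independent replicates). The median log2 ratio went from 0.09 in the lowest GC decile to -0.17 in the highest. After this trend was subtracted the median of the same 11 genes went from -0.52 to -0.30.

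**Figure D2:**
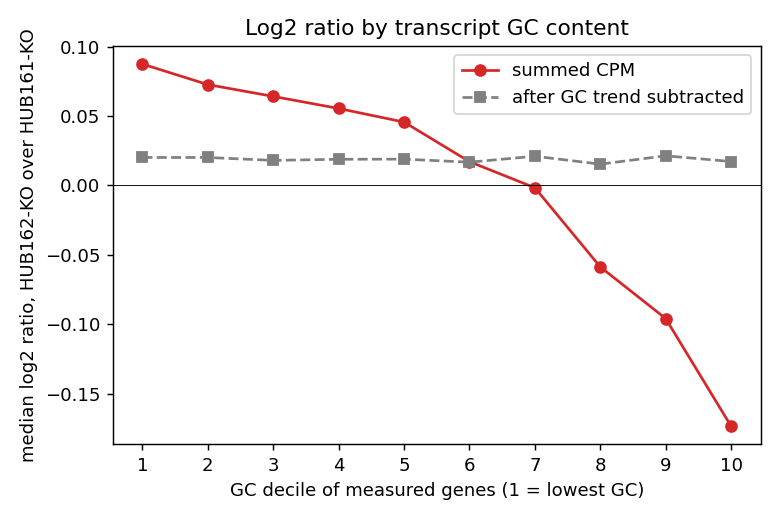
Measured genes are split into 10 equal groups by transcript GC content (x axis), and the y axis gives the median log2 ratio of HUB162-KO over HUB161-KO. Red circles run from 0.09 in the lowest group to -0.17 in the highest, and grey squares show the same genes after the trend was subtracted.

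The lists of protein synthesis, of the stress response that slows it and of the mitochondrial genome had medians slightly below 0, with members on both sides. Among 34 lists with enough measured genes, 4 had medians below and 1 above the central 95% of random lists. The 13 genes encoded by the mitochondrial genome had a median log2 ratio of -0.18 (percentile 0.04), with 8 members below 0, among them MT-CYB (-0.37), MT-ATP6 (-0.36), MT-ND4 (-0.32) and MT-ND1 (-0.28). The members above 0 were MT-ATP8 (0.71), MT-ND4L (0.46), MT-ND6 (0.31), MT-ND3 (0.10) and MT-ND5 (0.02), so the genes did not move together. The lower mitochondrial share per cell, 2.45% against 2.87%, is built from the same genes and is not a separate observation. Translation factors had a median of -0.09 (percentile 0.08), with 21 of 36 members below 0, and EEF1G (-0.40), EIF3B (-0.35), EEF1D (-0.27) and EIF3D (-0.25) furthest from it. Genes of cytosolic ribosomal proteins had a median of -0.04 (percentile 1.87), with 48 of 82 below 0, led by RPL3 (-0.36), RPLP0 (-0.29), RPS19 (-0.28) and RPS9 (-0.28).

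The integrated stress response list, which holds targets of the transcription factor ATF4, had a median log2 ratio of -0.10, below each of 10000 random lists, with 19 of 30 members below 0. DDIT3 stood at 69.1 against 84.2 CPM (-0.28), the amino acid transporter genes SLC3A2 at 108 against 131 CPM (-0.28) and SLC7A5 at 33.0 against 39.4 CPM (-0.26), and NUPR1 at 12.2 against 14.5 CPM (-0.25). DDIT3 and NUPR1 also stood among the 10 leading genes of clusters 10 and 8, and at the same cluster mix in both libraries their log2 ratios were -0.15 and -0.16, against -0.23 for SLC3A2 and -0.25 for SLC7A5. The median of the list was then -0.08. With the GC trend subtracted its median was -0.02, at percentile 5, which is inside the central 95%. Genes downstream of BCR-ABL, STAT5 and MAPK signalling were the 1 list above, with a median of 0.08 (percentile 97.9) and 15 of 22 members above 0. They were led by SOCS1 (0.44), PIM2 (0.28), CCND2 (0.17) and IL2RG (0.14). This list stayed outside the central 95% in only 7 of 16 alternatives. No measured member of these 34 lists was 1.5-fold lower, but only 1 of all 10777 measured genes was. Some members were at least 1.5-fold higher, among them RPS29 (0.71).

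**Figure D3:**
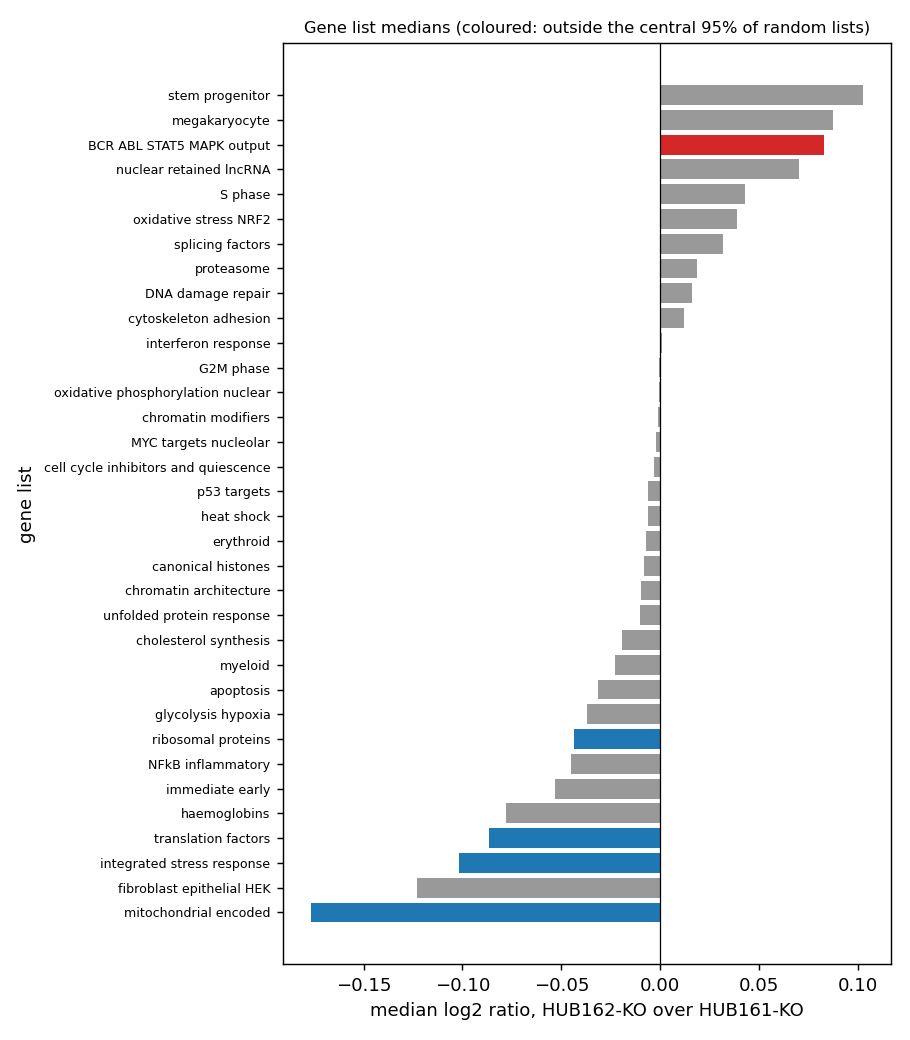
Bars give the median log2 ratio of HUB162-KO over HUB161-KO (x axis) for each of 34 gene lists (y axis). Blue bars are the 4 lists below and the red bar the 1 list above the central 95% of random lists, and the mitochondrially encoded genes have the lowest median at -0.18.

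The other 29 lists lay inside the central 95%. Haemoglobin genes, which K562 cells express, had a median of -0.08 (percentile 8.53), with HBG2 at 8514 against 9287 CPM and HBG1 at 6010 against 6419 CPM. Erythroid genes had a median of -0.01, with BLVRB at -0.23 and GYPC at -0.17. Targets of p53, the tumour suppressor gene product that responds to DNA damage, had a median of -0.01 (percentile 24.6), with XPC at 83.4 against 82.7 CPM and GADD45A at 76.1 against 75.4 CPM. DNA repair genes had a median of 0.02, with PRKDC at 0.11 and XRCC5 at -0.05. Genes of chromatin architecture had a median of -0.01, with HNRNPU at -0.04 and the heterochromatin protein gene CBX3 at 0.47. Apoptosis genes had a median of -0.03, with CYCS at 0.05 and BCL2L1 at -0.05. Of markers for other blood cells, 0 of 14 B lymphocyte genes were measured, and 1 of 19 T and NK cell genes, CD3D, at 61.7 against 63.9 CPM. Of 24 myeloid genes 5 were measured, with a median of -0.02, CST3 at 137 against 143 CPM and LYZ at 82.3 against 64.8 CPM. Of 28 megakaryocyte genes 11 were measured, with a median of 0.09 (percentile 94.9).

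The second comparison asked whether the cells were spread differently over the cell cycle. Phase shares were nearly equal. At 5000 UMIs per cell, 42.5% (41.5% to 43.5%, exact binomial) of 9907 HUB162-KO cells and 43.3% (42.1% to 44.5%) of 6784 HUB161-KO cells scored as G1. S phase held 31.8% (30.8% to 32.7%) and 31.2% (30.1% to 32.3%), and G2M held 25.7% (24.9% to 26.6%) and 25.5% (24.5% to 26.6%). Thinning left out 329 HUB162-KO cells and 0 HUB161-KO cells, and 1124 and 800 cells lay near the score boundary of G1. Without thinning G1 held 38.7% and 38.4%. The S phase list had a median log2 ratio of 0.04 (percentile 82.8), with TYMS at 0.24 and NASP at -0.12, and the G2M list a median of -0.0004 (percentile 16.5), with TOP2A at 0.33 and JPT1 at -0.08.

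The third comparison asked whether cell states were represented equally. All 12 clusters held cells of both libraries. Cluster 5, erythroid-like by 6 of its 10 leading genes (AHSP, HBZ, ALAS2, HBA2, HBG2 and HBE1), held 8.69% of HUB162-KO cells (8.16% to 9.26%) and 13.9% of HUB161-KO cells (13% to 14.7%). Cluster 7, erythroid-like by 5 leading genes and with a median mitochondrial share of 0.186%, held 5.70% and 5.98%. Cluster 10, unnamed and led by GADD45B, JUN and RRAD, held 4.39% (4% to 4.80%) and 6.22% (5.66% to 6.82%). Cluster 6, unnamed and led by BMP6 and RCAN3, held 9.52% (8.95% to 10.1%) and 7.05% (6.45% to 7.68%). Cluster 8, unnamed and led by SPRR2D, NRXN3 and NUPR1, held 5.54% and 5.41%. Clusters 5 and 10 held shallow cells, with medians of 9632 and 9095 UMIs in HUB162-KO, while cluster 6 held deep ones at 22278.

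**Figure D4:**
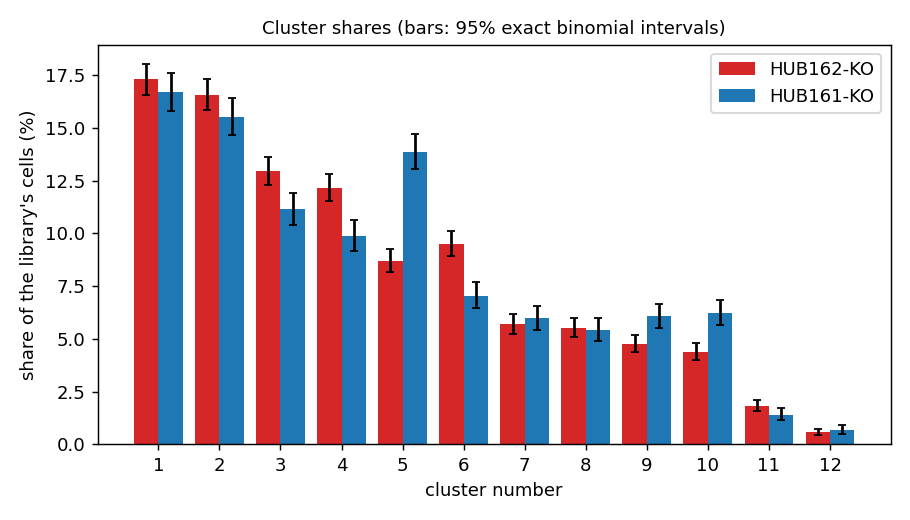
Bars give the share of each library's cells (y axis, %) in each of 12 clusters (x axis), red for HUB162-KO and blue for HUB161-KO, with 95% exact binomial intervals. Cluster 5 holds 8.69% against 13.9%, and cluster 6 holds 9.52% against 7.05%.

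The fourth comparison looked along the chromosomes, since Cas9 cutting can alter copy number. The window of 25 genes with the lowest median log2 ratio, -0.25, lay on chromosome 8 from 144051266 to 144525172 (GRCh38), between OPLAH and LRRC14. It was lower than in each of 1000 shuffles, and its genes had a median GC of 65.0%. The highest window, at 0.17, lay on chromosome 5 from 83077498 to 96631085, starting at the DNA repair gene XRCC4, and 13 of 1000 shuffles reached as high. With the GC trend subtracted the lowest window was on chromosome 9 (-0.07, reached in 401 of 1000 shuffles) and the highest on chromosome 5 from 7851186 to 32110932 (0.15, 46 of 1000). With GC content from longest transcripts the highest was on chromosome 18 instead (0.13, 295 of 1000) and the lowest on chromosome 11 (-0.11, 5 of 1000), so no region stood apart in every version. Whole-chromosome medians ran from -0.09 for chromosome 19 to 0.07 for chromosome 4.

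The deposited table of summed counts gave nearly the same ratios. It held 93.7% of the counts in HUB162-KO cells and 64.5% of those in HUB161-KO cells for the genes it shared with the matrices. Its log2 ratios correlated with those of the matrices over 10747 genes (Pearson 0.990, across genes). From it 12 genes were at least 2-fold higher in HUB162-KO and 0 at least 2-fold lower. The table sums UMIs of the same 2 libraries, so this likeness is not separate evidence. It held 0 mitochondrial genes, so the lower mitochondrial list could not be looked up there.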

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

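The GC and length corrections, the window of 12000 to 20000 UMIs, the omission of the deepest cells or of single clusters, the equal cluster mix, the deposited table and 4 of the cluster settings were chosen after seeing the data. The number of genes at least 2-fold higher in HUB162-KO, 13, was 54 at a mean CPM of at least 1 and 6 at a mean CPM of at least 20, by construction of the gene set, and stayed within 1.5 times of 13 in the other alternatives run. The number at least 2-fold lower was 0 in each alternative except cells of 12000 to 20000 UMIs, where it was 1. That window lies around the HUB162-KO median of 14051 UMIs per cell but below the HUB161-KO median of 20706. The lists outside the central 95%, 5 in all, were 15 in that window, 8 with the GC trend of canonical transcripts subtracted, 5 with that of longest transcripts and 3 in the deposited table, which has no mitochondrial genes and so gave medians for 33 lists instead of 34. The mitochondrial list stayed below in 15 of 15 alternatives, translation factors in 15 of 16, ribosomal proteins and the integrated stress response in 12 of 16 each, and the signalling list above in 7 of 16. Of 456 values of the 24 named genes 372 stayed inside their counting interval and 0 changed sign.

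The median UMIs per cell were 14315 and 20318 with a minimum of 5000. Phase shares moved alike in both libraries. Without thinning HUB162-KO had 38.7% G1, 32.7% S and 28.6% G2M cells, and HUB161-KO 38.4%, 32.6% and 29.1%. At 2500 UMIs the shares were 47.3%, 28.5% and 24.2%, and 48.5%, 27.9% and 23.5%. The highest window was 0.22 and the lowest -0.27 at a mean CPM of at least 1. The lowest was -0.074 with the GC trend subtracted, -0.11 with that of longest transcripts (chromosome 11, reached in 5 of 1000 shuffles, against 401 with canonical transcripts) and -0.084 with GC and length subtracted. The highest was reached in 46, 295 and 134 of 1000 shuffles in these 3 versions, so whether either corrected window stood apart depended on the version. The cluster with most erythroid-like markers, which was not the same cluster in each setting, had shares of 15.9% and 22% at 0.5 times the resolution, 7.79% and 12.8% at 1.5 times, 14.7% and 18.6% with library means removed, and 13.8% and 22.3% with cells thinned to 5000 UMIs, where a second erythroid-like cluster was larger in HUB162-KO (8.71% and 7.97%). Cluster 5 itself held 7.45% and 12.5% of cells with at least 0.5 of their library's median UMIs, and 6.85% and 13.3% at 8000 UMIs or more. The causes of these moves were not tested.

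No paired analysis was possible because each group held 1 library. Subtraction of the empty-droplet profile was not run, since the estimated share of free RNA reached its upper limit of 50% in both libraries. With 1 library per group, the missing replicates limited all named ratios.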

Other observations

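Several abundant transcripts outside the leading genes differed by more than their list, and they are named here after their values were seen. The nuclear RNA MALAT1 stood at 10784 CPM in HUB162-KO and 7728 CPM in HUB161-KO (log2 0.48). Among erythroid genes the transferrin receptor gene TFRC (265 against 190 CPM, log2 0.48) and RHAG (162 against 122 CPM, log2 0.41) were higher in HUB162-KO, while the list's median was -0.01. Within the integrated stress response list, whose median was -0.10 but -0.02 with the GC trend subtracted, the tRNA synthetase genes SARS (log2 0.52) and NARS (0.53) were higher. Within the ribosomal and mitochondrial lists RPS29 stood at 3947 against 2408 CPM (log2 0.71) and MT-ATP8 at 117 against 71.9 CPM (0.71). Of the 89 genes at least 1.5-fold higher in HUB162-KO 24 were long noncoding RNA, against 972 of 10777 measured genes, and 1 gene was at least 1.5-fold lower. These counts depended on the settings, with 71 higher and 4 lower under the TMM factor, and 163 and 29 in cells of 12000 to 20000 UMIs. They were 281 and 12 at a mean CPM of at least 1, where 14685 genes were measured.

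For the 3 patterns below, all tests were chosen after the patterns had been seen. The first pattern is that log2 ratios were lower at higher GC content, a Spearman correlation of -0.51. In cells of 12000 to 20000 UMIs the correlation was -0.43, so it remained among cells of like UMI totals. That window lies around the HUB162-KO median of 14051 UMIs but below the HUB161-KO median of 20706, so a difference in depth stays open. A different mix of cell states is argued against, since the correlation was -0.51 at the same cluster mix. Over 82 ribosomal protein genes the correlation was -0.60, which a sequence-dependent yield of one of the libraries would also give. These genes are among those that show the trend, so the value cannot separate such a yield from another cause. The hub that was targeted stays open as an untested explanation, because each hub had 1 library.

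The second pattern is that 13 genes were at least 2-fold higher and 0 at least 2-fold lower. After both the GC and the length trend were subtracted 11 of the 13 stayed at least 2-fold higher, with MAFIP not evaluable for lack of a GC value, so these trends do not account for most of them. At the same cluster mix 12 stayed, which argues against a different mix of cell states. A difference between 2 cell preparations or between clones, and an effect of the targeted hub, stay open and were not tested.

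The third pattern is the smaller share of erythroid-like cluster 5 in HUB162-KO, a difference of -5.16 percentage points. The difference was -5.06 among cells with at least 0.5 of their library's median UMIs, a minimum that still differed between the libraries. At a common minimum of 8000 UMIs it was -6.48. That cut kept 8658 of 10236 HUB162-KO cells and 6548 of 6784 HUB161-KO cells, and cluster 5 held shallow cells. The smaller share thus remained under both cuts, but neither settles whether the UMI minimum played a part. A difference in depth is argued against by a difference of -8.51 after thinning to 5000 UMIs, although a second erythroid-like cluster then held 8.71% against 7.97%. An offset between the libraries stays open, since with library means removed the difference was -3.86 in a larger cluster, and the ratio of the shares went from 0.628 to 0.793. Culture, sorting and the targeted hub stay open and were not tested.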
